A study of Rattus norvegicus with 9 samples.

How the data were processed

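Total RNA of rat lung was extracted with Trizol and kept where its RNA integrity number was at least 6, and biotinylated copies made from 50 ng were hybridised, per the labels' protocols. The deposited table holds log2 expression values, 1 column per array and 1 row per transcript cluster. R 2.11.0, RMA and limma are named in the submitters' processing notes, with no role or order given. The genome build is not given in the sources used here. RMA, as generally used, corrects the background, quantile normalizes the probe intensities of all arrays together and summarises each transcript cluster on the log2 scale. The deposited log2 values have nearly equal medians on all 9 arrays, but their spread differs, with an SD between 1.76 and 1.94.

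The labels give 3 MetS and 4 control rats, with a technical replicate for MetS animal 1 and one for control animal 1; at which step the technical replicates were split is not given in the sources used here. The 2 arrays of such an animal were averaged first, so that n counts animals. The group comparison was a linear model of the log2 values with empirical Bayes moderation (lmFit and eBayes of limma 3.58.1 in R 4.3.3), MetS minus control, with Benjamini-Hochberg adjustment over all 28826 probes and a threshold of 0.05. The moderated test had 7.28 degrees of freedom, 5 of them from the animals. Exact permutation tests and correlations were computed with scipy 1.17.1 and numpy 2.4.6 in Python 3.11.15, tables with pandas 2.3.3 and figures with matplotlib 3.10.9.

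Probes were named through the platform's annotation table, with symbols updated through the gene identifiers of the RefSeq annotation of assembly GRCr8, of which only names were used. Exactly 1 gene symbol was given for 15209 probes (52.8%), several for 306 and none for 13311, which are unnamed here. Of the 15209, 15184 matched a current RefSeq gene and 25 kept the array's symbol. They stand for 14498 genes, 493 of them with more than 1 probe; the probe with the highest mean over the animals stood for the gene. For 8 genes, Armc2, Btn3a2, Gapdh, Gnrh1, Hnrnpa3, LOC108353138, Rbm39 and Sh3bp4, another probe with an unadjusted p under 0.05 had the opposite sign; none of them is described.

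Gene lists of cell types, processes, gene families and RNA classes were fixed before the data were examined, as were the main tests, 16 alternative settings and the rule for named genes. Of 57 lists, 4 had under 5 measured genes and were not tested, which left 53. Lists were tested with camera of limma with a preset inter-gene correlation of 0.01, Benjamini-Hochberg adjusted over the 53 lists. An estimated correlation, ranks and fry were alternatives. A list's place among 10000 random lists matched on brightness was taken as a description and was not computed for the olfactory list, the longest. The random lists could draw receptor genes, which are dim and lower in MetS.

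The rule for named genes took genes past the adjusted threshold whose groups did not overlap. As none passed, it was filled in each direction with the 10 widest differences among probes with 1 symbol that is no placeholder, a mean above the 25th percentile of probe means (6.48), an unadjusted p under 0.01 and no overlap. Added were the up to 4 members of each called list with the smallest p, up to 2 of each other list, list members that passed when adjusted over the list alone, and 9 genes of vascular tone, lung epithelium and metabolism taken whatever their value. The receptor genes that passed over their lists alone are given as counts, since there were 731 of them. The rule as fixed took those 2 only where the text describes the list. The 145 genes tabulated hold them whether or not it does, and the text names only some of them. Which of the uncalled lists the text describes was chosen after the values were seen, and so were Tsc22d3 and the cardiomyocyte gene Actc1, which the rule does not name. The alternatives were counted for 94 genes, those in the text and the remaining members of called lists that the rule names.

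The gene test was tested on simulated data with the real probe means and SDs and 200 changed probes among 28826 in each of 5 runs. For MetS against control it recovered 78.4% of changes of 1 on the log2 scale, 95.2% of 2, 98.4% of 3 and 100% of 4, with 52 false calls over the 5 runs. The list test, run on 14498 simulated genes, recovered 15 of 15 lists shifted by 0.3 and called 1 of 215 others. These simulated values carried no spread shared between probes of an array, which the real arrays have.

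The alternatives were the first array of each animal alone, all 9 arrays with the animal as a random block, another quantile normalization, centring on the median, filters on dim or unnamed probes, other moderation, array weights, the replicate number as a block, leaving out each animal, other thresholds and other list tests. Added after seeing the data were fits without controls 2 and 3, with the SD of each animal's values as a covariate, with a clock index as a covariate, and list tests without the receptor genes. The clock index is the mean of Dbp and the genes that peak with it minus the mean of Bmal1 and the genes that peak with it. No sample was left out of the main comparison.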

Results

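Lung RNA was measured in 7 Wistar rats, 3 of them with metabolic syndrome (MetS) and 4 controls. The MetS animals had drunk a 30% sucrose solution as their only liquid for 24 weeks, and the controls had drunk water, with the same chow for both groups. The growth protocol in the labels names fasting conditions for 7 hours, and an effect of feeding state was not tested. Each sample was hybridised to a whole-transcript Affymetrix rat gene array, which gives one value per transcript cluster, called a probe here. MetS animal 1 and control animal 1 each had 2 arrays in the labels, so that 9 arrays stood for 7 animals. The table held 28826 probes, with array medians between 7.64 and 7.69 on the log2 scale. The labels call the MetS rats male and give no sex for the controls, so a difference in sex between the groups is not excluded. Animals were the replicates throughout, and their number limits the precision of every value below.

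The question was which lung genes differed between rats with metabolic syndrome and controls. Of 20 genes that respond to glucocorticoid hormone 17 were higher and 3 lower in MetS, a list that camera called (adjusted p = 0.00519) but not with an estimated correlation between genes (adjusted p = 0.988). Among them Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 9.37 ± 0.41 (SD, n = 3) against 8.51 ± 0.22 (SD, n = 4) in controls, a 1.82-fold difference. Them5, an acyl-CoA thioesterase, stood at 9.67 ± 0.59 against 8.43 ± 0.16, a 2.36-fold difference and the widest higher value among the named genes. Lower in MetS were the immediate early transcription factor Egr1 at 8.73 ± 0.14 against 9.57 ± 0.36, the lymphatic growth factor Vegfd at 7.69 ± 0.28 against 8.45 ± 0.26, and the lipid carrier Apoe at 10.46 ± 0.08 against 10.81 ± 0.08. Olfactory and vomeronasal receptor genes, which code for the odour and pheromone receptors of the nose, read lower in MetS, with a median olfactory difference of -0.66, but -0.08 with the spread of the arrays in the fit. Neither family was called with an estimated correlation (adjusted p = 0.988 for each). No single one of these genes passed the test over all probes, so the values describe these 7 animals, in which the 3 MetS values and the 4 control values of each named gene above did not overlap. These genes were named by rules that asked for no overlap or a small p, and 11.7% of all probes did not overlap.

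With limma, 0 probes were higher and 0 lower at an adjusted p under 0.05, and the smallest adjusted p was 0.324. At an unadjusted p under 0.05 there were 1102 probes higher and 2857 lower in MetS, 3959 in all or 13.7% of the probes, where 1441 would come up by chance among independent probes. With a fold of at least 1.5 as well, 95 were higher and 1453 lower. The animals of the groups did not overlap for 3380 probes, 11.7%, against a chance share of 5.7%. Quantile normalizing the arrays again turned the split at the unadjusted threshold to 2312 higher and 1993 lower. These counts moved by over 1.5 times when single animals were left out: the higher count became 666 without MetS animal 2, 524 without control 2, 611 without control 3 and 2016 without control 4. The lower count became 1354 without MetS animal 1, 1502 without MetS animal 2, 1862 without control 2 and 1710 without control 3.

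Of the genes with the widest differences, 10 in each direction were taken by a fixed rule and are given as values. Besides Them5 and Fkbp5, the higher ones were RT1-N2, a class I histocompatibility gene, at 1.98-fold, Zbtb16 at 1.53-fold, Tmem252 at 1.42-fold, the survival gene Bcl2l1 at 1.36-fold, Spsb1 at 1.36-fold, Klf9 at 1.35-fold, the lysophosphatidic acid receptor Lpar1 at 1.35-fold and Cyp2t1 at 1.35-fold. The lower ones were Spetex2g, at 6.32 ± 0.69 in MetS against 8.63 ± 0.86 in controls, and 9 olfactory receptors, Or5p60b, Or4f60b, Or9r3b, Or9k2b, Or52j3b, Or4a15, Or8b101c, Or5b124 and Or4c120. Their log2 differences lay between -2.03 for Or5p60b and -1.68 for Or4c120. Every one of the 20 had an adjusted p of 0.324 in limma. With the SD of each animal's values in the fit 18 of the 20 differences were smaller by over 1.5 times. Examples were RT1-N2 from 0.99 to 0.56, Fkbp5 from 0.86 to 0.47, Tmem252 from 0.51 to 0.21 and Or5p60b from -2.03 to -0.61. Them5 went from 1.24 to 1.48 and Zbtb16 from 0.62 to 0.52. The SD followed the main axis between the animals, with a Pearson r of -0.993 with the first principal component. The MetS animals lay toward one end of that axis. A smaller difference with the SD in the fit therefore does not decide between array spread and a difference of the groups, here or below.

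**Figure D1:**
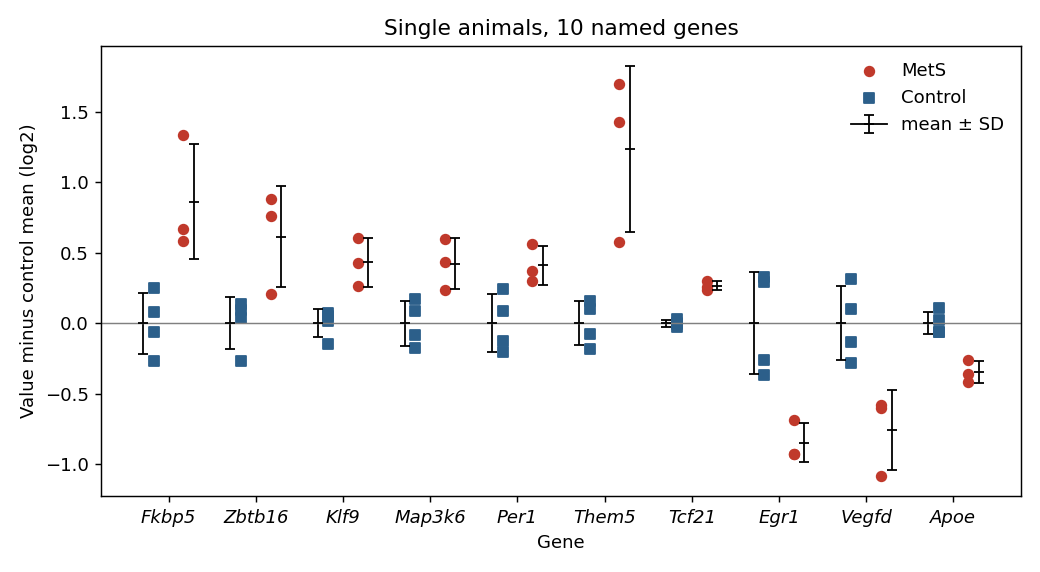
Value of each animal minus the control mean, on the log2 scale, for 10 named genes, with circles for the 3 MetS animals, squares for the 4 controls and bars for the mean ± SD of each group. For each gene the MetS circles lie wholly above or wholly below the control squares, as for Tcf21 at 9.60 ± 0.03 against 9.34 ± 0.02. The genes were picked from those named for no overlap or a small p, so the separation follows from the choice. Of all probes 11.7% did not overlap.

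The glucocorticoid response list, a set of 20 measured genes that corticosteroids are known to induce or regulate, was higher in MetS, with 17 members higher and 3 lower and a mean difference of 0.27 against -0.03 over all other genes (camera in limma, adjusted p = 0.00519). With an estimated correlation between the genes the call was lost (adjusted p = 0.988), and the fry test gave an adjusted p of 0.576. That 0.988 was the smallest adjusted p of any list with an estimated correlation, and this list had an unadjusted p of 0.0743 there (camera). Adjusted over the list alone, 4 members passed, each higher in MetS: Klf9, a Krüppel-like transcription factor, at 9.64 ± 0.17 against 9.20 ± 0.10 (adjusted p = 0.0338), Fkbp5 (adjusted p = 0.0338), the kinase gene Map3k6 at 8.67 ± 0.18 against 8.25 ± 0.16 (adjusted p = 0.0484) and the zinc finger gene Zbtb16 at 10.43 ± 0.36 against 9.81 ± 0.19 (adjusted p = 0.0484). Over all probes 0 members passed. The median of the list against the control mean was 0.33, 0.21 and 0.22 in the MetS animals and 0.09, -0.02, -0.11 and 0.14 in controls 1 to 4. The mean of the list relative to all other genes differed by 0.301 (two-sided exact permutation test over 35 splits, p = 0.0571, adjusted p = 0.0857 over 3 such tests). With 3 and 4 animals this p is the lowest the test can give, so the test could not pass 0.05 and does not decide. The clock gene Per1, also a hormone target, stood at 9.55 ± 0.14 against 9.14 ± 0.20, and Tsc22d3, which codes for the glucocorticoid-induced leucine zipper and was picked after its value was seen, at 10.80 ± 0.27 against 10.20 ± 0.43. The difference of Tsc22d3 went from 0.60 to 0.13 with the SD of each animal's values in the fit and to 0.34 without controls 2 and 3. Pdk4, which restrains glucose oxidation, stood at 9.42 ± 0.51 against 9.06 ± 0.83, within the spread of the controls. With the SD of each animal's values as a covariate, the median difference of the list went from 0.28 to 0.07, while the call was kept (adjusted p = 0.039). Over the 7 animals the SD and the mean of the list had a Pearson r of 0.796 (exact permutation p = 0.0379, adjusted p = 0.0379 over 3 relations) and a Spearman rho of 0.714 (p = 0.0881, adjusted p = 0.0881). Without the 2 animals farthest from the median r was 0.512. The 5 animals left span a narrower range of SD, so how far the relation rests on those 2 is open. The correlation pools both groups, whose means differ in both measures, so it does not separate the SD from the group.

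The cell cycle list was higher as well, with 23 of its 24 measured members higher and a mean difference of 0.18 (camera, adjusted p = 0.00145, and adjusted p = 0.988 with an estimated correlation). Top2a, the topoisomerase of dividing cells, stood at 8.44 ± 0.14 against 8.04 ± 0.16, the spindle gene Nusap1 at 7.54 ± 0.05 against 7.20 ± 0.17, the mitotic kinase gene Cdk1 at 6.64 ± 0.04 against 6.40 ± 0.10, and the spindle gene Tpx2 at 7.62 ± 0.09 against 7.39 ± 0.09. None of the 24 passed when adjusted over the list alone or over all probes. Relative to all other genes the list mean was 0.21, and it was 0.10 with the SD in the fit (adjusted p = 0.0336) and 0.12 without controls 2 and 3 (adjusted p = 0.00292).

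The olfactory receptor list had 1086 of 1098 measured genes lower in MetS, with a median difference of -0.66 (camera, adjusted p = 4.57e-108). The vomeronasal receptor list had 133 of 134 lower, with a median of -0.69 (adjusted p = 7.21e-47). Both calls were lost with an estimated correlation (adjusted p = 0.988 for each), which was 0.785 within the olfactory list. Before adjustment camera with the estimated correlation gave p = 0.0451 for the olfactory and p = 0.0768 for the vomeronasal list. By animal, the olfactory median was 5.69 ± 0.19 in MetS against 6.44 ± 0.44 in controls (two-sided exact permutation test over 35 splits, p = 0.0571, adjusted p = 0.0857). That p is the lowest the test can give with 3 and 4 animals, so the test could not pass 0.05 and does not decide. Adjusted over the list alone, 626 olfactory and 105 vomeronasal genes passed, and 0 passed over all probes. Among those with the smallest p, Or5ac22 stood at 5.45 ± 0.12 in MetS against 6.05 ± 0.16 in controls, Or4k15c at 5.18 ± 0.13 against 6.03 ± 0.27, Vom2r33 at 3.63 ± 0.04 against 4.06 ± 0.12 and Vom1r23 at 5.69 ± 0.10 against 6.63 ± 0.38. The 2 families held 930 of the 3959 probes at an unadjusted p under 0.05, all of them lower.

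These receptor genes moved with the spread of values on the arrays. The SD over all probes was 1.93, 1.90 and 1.88 in the MetS animals and 1.85, 1.77, 1.76 and 1.88 in controls 1 to 4, and the median olfactory receptor value was 6.83 in control 2 and 6.76 in control 3 but 5.91 in control 4, next to 5.90 in MetS animal 3. The mean SD was 1.90 ± 0.03 in MetS and 1.81 ± 0.06 in controls (two-sided exact permutation test over 35 splits, p = 0.114, adjusted p = 0.114). With the probes in 10 groups by brightness, the dimmest group had a median difference of -0.13 and the group next to the brightest one of 0.09. With the SD in the fit the median olfactory receptor difference was -0.08, and without controls 2 and 3 it was -0.33; these 2 settings gave 483 higher with 540 lower probes, and 413 higher with 1097 lower probes, at an unadjusted p under 0.05.

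**Figure D2:**
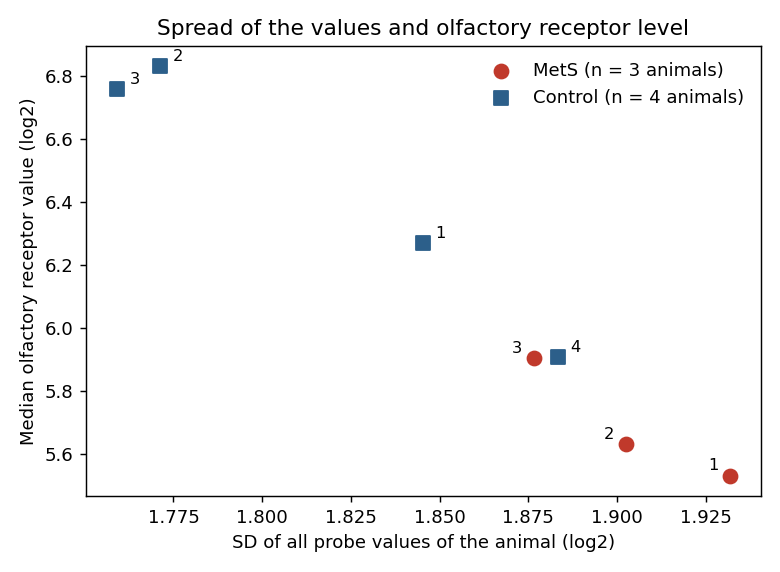
Median olfactory receptor value of each animal against the SD of all its probe values, both on the log2 scale, with circles for the 3 MetS animals, squares for the 4 controls and the animal number beside each point. Controls 2 and 3, with SDs of 1.77 and 1.76, have the highest medians, and control 4, with 1.88, lies beside MetS animal 3.

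Another 4 lists were called lower by camera, each with small differences, and all 4 calls were lost with an estimated correlation (adjusted p = 0.988 for each). Among random lists matched on brightness, ranked from lowest to highest mean, the P450 list lay at percentile 91.32 and the cartilage list at 32.83. The histone list lay at 2.28, the ribosomal and vomeronasal lists at 0, and the glucocorticoid and cell cycle lists at 100. The random lists could draw receptor genes, so for dimmer lists, such as P450 and cell cycle, the place does not decide. Without the receptor genes camera called all 4 lower. The adjusted p was 2.71e-06 for P450, 5.18e-05 for ribosomal, 0.000815 for histone and 0.00215 for cartilage genes. In that order the calls held in 17 of 24, 16 of 24, 15 of 24 and 7 of 23 alternatives. The cytochrome P450 list, a family of oxidising enzymes, had 44 of 68 genes lower with a mean difference of -0.11 (adjusted p = 0.00519), and its direction turned when the arrays were quantile normalized again (adjusted p = 0.968) or the SD was in the fit (adjusted p = 0.0591). The P450 call was also lost without controls 2 and 3 (adjusted p = 0.466). Its members went both ways: Cyp2c6v1 stood at 5.52 ± 0.35 in MetS against 7.01 ± 0.75, and Cyp11b1 at 4.66 ± 0.13 against 4.96 ± 0.12, whereas Cyp2d4 stood at 7.91 ± 0.18 against 7.63 ± 0.09. Without controls 2 and 3 the Cyp2c6v1 difference went from -1.50 to -0.86, Cyp11b1 from -0.29 to -0.25 and Cyp2d4 from 0.29 to 0.24. Ribosomal protein genes were lower in 58 of 81 cases with a mean difference of -0.03, equal to that of the other genes at 2 decimals (adjusted p = 0.0315), with Rpl7a at 11.69 ± 0.16 against 11.90 ± 0.08 and Rpl9 at 11.87 ± 0.10 against 12.03 ± 0.05. The same name pattern took 6 genes named as S6 kinases, which are no part of the ribosome. Of these Rps6kb1 stood higher, at 9.07 ± 0.05 against 8.90 ± 0.08, and so did Rps6ka5, at 9.20 ± 0.14 against 8.94 ± 0.16. The ribosomal call was lost without MetS animal 3, where the direction turned (adjusted p = 0.776), and without control 4 (adjusted p = 0.313). Histone genes were lower in 18 of 22 cases with a mean of -0.07 (adjusted p = 0.0449), with H2bc12 at 8.20 ± 0.13 against 8.38 ± 0.13 and H1f4 at 10.74 ± 0.22 against 10.92 ± 0.07. The histone call was lost without MetS animal 1 (adjusted p = 0.071), MetS animal 3 (adjusted p = 0.401) or control 4 (adjusted p = 0.44). Cartilage markers were lower in 8 of 9 cases with a mean of -0.11 (adjusted p = 0.0495), with Hapln1 at 6.22 ± 0.13 against 6.52 ± 0.19 and Col9a1 at 7.32 ± 0.10 against 7.53 ± 0.13. The cartilage call was lost without MetS animal 1 (adjusted p = 0.0888), MetS animal 2 (adjusted p = 0.069), control 2 (adjusted p = 0.0744), control 3 (adjusted p = 0.233) or control 4 (adjusted p = 0.0631), and its direction turned with the SD in the fit (adjusted p = 0.332). Without controls 2 and 3 together the cartilage list had an adjusted p of 0.841.

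In all, camera called 2 of the 53 lists higher and 6 lower, and with an estimated correlation or with fry it called 0. By fry 4 lists had an unadjusted p under 0.05, those of glucocorticoid response, cell cycle and both receptor families. Leaving out 1 animal moved the number called higher to 10 without MetS animal 1, 4 without MetS animal 2, 6 without MetS animal 3 and 4 without control 1, and the number called lower to 3 without control 4. Every other split of the 7 animals into 3 and 4 gave between 7 and 22 called lists with the preset correlation.

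**Figure D3:**
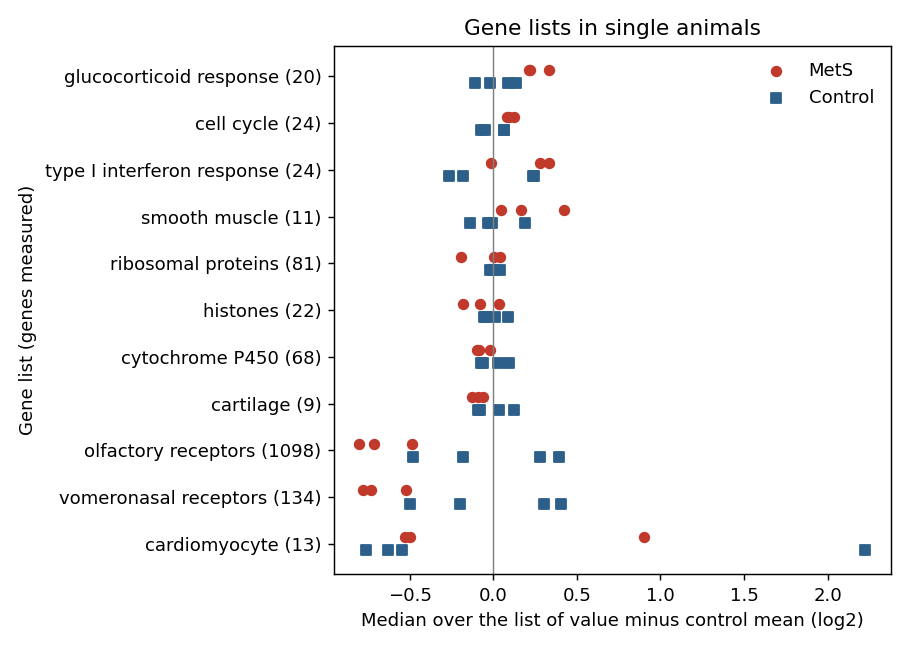
Median over each gene list of the animals' values minus the control mean, on the log2 scale, with circles for the 3 MetS animals, squares for the 4 controls and the number of measured genes after each list name. The olfactory receptor medians of controls 2 and 3 lie farthest to the right within that list, and the cardiomyocyte list has control 1 alone at 2.23.

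Markers of the lung's own cells differed by less than the spread of the animals or did not pass the test. Sftpc, the surfactant protein of alveolar type 2 cells, stood at 13.89 ± 0.01 in MetS and 13.89 ± 0.01 in controls, and Scgb1a1, the secretoglobin of airway club cells, at 13.73 ± 0.04 and 13.76 ± 0.04, both near the top of the array's range of 14.2, where differences are compressed. Sftpd, another surfactant protein, stood at 12.18 ± 0.06 against 11.95 ± 0.16. Scgb3a1, a secretory airway gene, stood at 10.18 ± 0.24 against 11.47 ± 0.91 and Retnla, a resistin-like secreted protein, at 11.45 ± 0.88 against 10.56 ± 0.40, with overlapping groups. Tcf21, a transcription factor of lung fibroblasts, was the 1 fibroblast and pericyte marker of 12 that passed when adjusted over the list alone; it did not pass over all probes (limma, adjusted p = 0.324). Apoe was the 1 gene of 18 in the surfactant lipid and cholesterol transport list to do so, and neither list was called (camera, adjusted p = 0.238 for the first and 0.856 for the second). The first was called without MetS animal 1 (adjusted p = 0.0195), and the second was called lower with the SD in the fit (adjusted p = 0.00495). The mean of the second list was -0.00109 and its median 0.0125, so that they differ in sign.

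No list of vascular tone, sugar use, insulin signalling or fat synthesis was called. For vascular tone and pulmonary pressure 18 of 28 genes were higher (camera, adjusted p = 0.965) and for glycolysis 9 of 16 (adjusted p = 0.908). For sucrose and fructose use 3 of 12 were higher (adjusted p = 0.424), a list called lower among probes above the 25th percentile (adjusted p = 0.0448) or above the median of probe means (adjusted p = 0.00895) but not in the other 22 of 24 alternatives. For insulin and IGF signalling 17 of 19 were higher (adjusted p = 0.0666). The insulin list was called without MetS animal 3 (adjusted p = 0.0366) or control 1 (adjusted p = 0.0184). Its mean relative to other genes went from 0.17 to 0.02 with the SD in the fit (adjusted p = 0.572). The glycolysis list was called lower with the SD in the fit (adjusted p = 0.00552). Nos3, the endothelial nitric oxide synthase, stood at 7.77 ± 0.16 in MetS against 7.67 ± 0.10, and the angiotensin-converting enzyme gene Ace at 12.12 ± 0.31 against 11.95 ± 0.13. The endothelin gene Edn1 stood at 10.61 ± 0.12 against 10.48 ± 0.54, and its direction turned without control 3. The angiotensin receptor gene Agtr2 stood at 6.01 ± 0.08 against 6.43 ± 0.23 and the serotonin receptor gene Htr2a at 6.58 ± 0.14 against 6.82 ± 0.12. Without controls 2 and 3 the Agtr2 difference went from -0.42 to -0.23 and that of Htr2a from -0.25 to -0.29. The fatty acid synthase gene Fasn stood at 11.01 ± 0.38 against 10.62 ± 0.17, and in its list of fatty acid and triglyceride synthesis 15 of 18 genes were higher (camera, adjusted p = 0.125, 0.0237 without MetS animal 2 and 0.671 without MetS animal 1). With the SD in the fit its mean relative to other genes went from 0.17 to 0.0029 (adjusted p = 0.908), and Fasn from 0.39 to 0.11. Adipoq, the adipocyte hormone adiponectin, stood at 6.79 ± 0.09 against 6.84 ± 0.14. Il6, an inflammatory cytokine, was dim at 5.12 ± 0.02 against 5.45 ± 0.21, and its difference went from -0.34 to -0.19 without controls 2 and 3. In its list of inflammatory cytokines 6 of 20 were higher and 14 lower (camera, adjusted p = 0.17), called lower in 6 of 24 alternatives, among them with the SD in the fit (adjusted p = 0.00186) and without control 3 (adjusted p = 0.031). The limma adjusted p of these genes lay between 0.324 for Agtr2 and 0.838 for Edn1.

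The arrays of one animal were closer to each other than those of different animals. Their Pearson correlation across probes, which are not independent replicates, was 0.995 and 0.997, against 0.977 to 0.990 between different control animals and 0.988 to 0.992 between different MetS animals. The SD of the differences between the 2 arrays of an animal was 0.142 and 0.181, against a median of 0.347 between control animals and 0.260 between MetS animals.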

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

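The 94 genes whose alternatives were counted, the median of each tested list and 3 measures per animal were tested for 1 control standing apart from the other 3, by the gap to the nearest control over the range of the group; Actc1 was added to this test after its values were seen. Of 150 results 6 exceeded Dixon's critical ratio at the 95% level, where chance at 1 in 20 gives about 7.5.

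The heart muscle actin gene Actc1 had a ratio of 0.955, with control 1 at 12.05 on the log2 scale and the other controls between 7.61 and 7.80, while MetS animal 1 stood at 10.72 and the other MetS animals at 8.34 and 8.40. The median of the cardiomyocyte list, against the control mean, had a ratio of 0.93, with control 1 at 2.23 and the other controls between -0.76 and -0.55, while the MetS animals stood at 0.90, -0.53 and -0.50. The endothelial nitric oxide synthase gene Nos3 had a ratio of 0.868, with control 3 at 7.82 and the others between 7.61 and 7.64. Ace, the gene of the angiotensin-converting enzyme, had a ratio of 0.918, with control 3 at 11.75 and the others between 12.00 and 12.02. Fmo2, a flavin monooxygenase of lung, had a ratio of 0.835, with control 4 at 11.64 and the others between 12.16 and 12.27. The median of the list of angiogenesis ligands and receptors had a ratio of 0.843, with control 4 at 0.0369 and the others between -0.0267 and -0.0167.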

How the results depend on the processing

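The fits without controls 2 and 3, with the SD of each animal as a covariate, with the clock index and without the receptor genes were added after the data were seen; the other 16 were set beforehand. With the replicate number as a block, 138 probes were higher and 1879 lower past an adjusted p of 0.05 in limma, with 2204 and 4543 at an unadjusted p under 0.05 and 3 lists called lower. The correlations of like-numbered animals were 0.271, -0.118 and 0.339, against -0.421 to 0.385 for animals of unlike number. These few values do not decide whether the numbers pair the animals. Nothing is concluded from this fit, though its values are counted and printed among the alternatives. Only control 4 has its number, so the group differences equal those without control 4 (median over all probes 0.0164 in both). Why more probes passed with the block was not tested. In every other alternative run on probes, 0 passed an adjusted p of 0.05, with the smallest adjusted p at 0.0522 without control 4.

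At an unadjusted p under 0.05, quantile normalizing again gave 2312 higher, 1 symbol per probe gave 661 higher and 1435 lower, a fold of at least 1.5 gave 95 and 1453, probes above the 25th percentile gave 1131 lower and those above the median 365 lower. The filters on symbol and brightness test fewer probes, and the fold adds a condition. Without controls 2 and 3 there were 413 higher and 1097 lower, and with the SD as a covariate 483 and 540. Leaving out each animal in turn gave 524 to 2016 higher and 1354 to 4164 lower, with 0 to 0 past the adjusted threshold in each direction. Lists called higher numbered 4 with the animal as a random block, 4 after quantile normalizing again, 4 with the mean of the probes of a gene, 8 with the SD as a covariate, and 0 with an estimated correlation or with fry. Lists called lower numbered 3 with the first array of each animal, centring on the median or array weights, 11 above the 25th percentile, 15 above the median, 12 with the SD as a covariate, and 0 with an estimated correlation or with fry. Without each animal in turn they ranged from 2 to 10 higher and from 3 to 7 lower; the causes were not tested.

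The glucocorticoid list kept its call in 22 of 24 alternatives, with an adjusted p from 0.00154 to 0.988. Relative to the other genes, the cartilage list turned to 0.0530 with the SD as a covariate, the ribosomal list to 0.0657 without MetS animal 3 (lowest without 1 animal -0.0478), and the cytochrome P450 list to 0.00133 after quantile normalizing again and 0.0683 with the SD as a covariate. Of 94 genes, 86 kept their sign in all alternatives, and 20 of 1737 values had the other sign. Sizes held less often: the difference was smaller by over 1.5 times for 58 of the 94 with the SD as a covariate, 34 without controls 2 and 3 and 15 after quantile normalizing again. With the SD as a covariate, the values of the other sign were Hapln1 at 0.00149, Matn1 at 0.0721, Snorc at 0.0639, Edn1 at -0.498, Sftpc at 0.0107, Scgb1a1 at 0.0324 and Actc1 at -1.16. Without controls 2 and 3 they were Edn1 at -0.252, Sftpc at 0.00143, Scgb1a1 at 0.00219, Matn1 at 0.00763 and Actc1 at -0.775. After quantile normalizing again they were Sftpc at 0.0430 and Adipoq at 0.0685, after centring Sftpc at 0.00395, and with array weights Actc1 at -0.715. Without 1 animal Edn1 ranged from -0.0557 without control 3 to 0.373, and Actc1 from -0.435 to 1.43, being -0.435 without MetS animal 1, -0.0502 without control 2 and -0.000175 without control 3; the causes were not tested. Camera's direction follows the test statistics of a list's genes, so it can turn while the mean relative to other genes keeps its sign. In the main fit that mean was 0.0554 for vascular tone, 0.0267 for glycolysis and 0.0271 for surfactant lipid transport. It was -0.029 for sucrose and fructose use, 0.0724 for hypoxia and 0.0978 for complement and coagulation. Among uncalled lists, camera's direction turned for vascular tone with the first arrays (mean relative to other genes 0.0596), array weights (0.0747), the replicate block (0.0828) and without controls 2 and 3 (0.0389). That direction also turned with the SD (0.0456), the clock index (0.0677) and fry (0.0554), with 0.0291 to 0.105 without 1 animal. The direction turned for glycolysis with the replicate block (0.0435) and fry (0.0267), with -0.0186 to 0.0758 without 1 animal. For surfactant lipid transport it turned with the replicate block (0.0553) and fry (0.0271), with -0.0302 to 0.0616 without 1 animal, and for sucrose and fructose use with the SD (-0.0146). It turned for hypoxia above the 25th percentile (0.00662), above the median (-0.0283), without controls 2 and 3 (-0.0485), with the SD (-0.138) and without receptor genes (0.00905). It turned for complement and coagulation after quantile normalizing again (0.0338), above the 25th percentile (0.0320), above the median (-0.0218), without controls 2 and 3 (0.0492), with the SD (0.0194) and without receptor genes (0.0344); the causes were not tested. The olfactory receptors were dim as a family, at a mean median of 5.69 in MetS and 6.44 in controls. Those with the widest differences were not all dim, as Or5p60b stood at 6.86 in MetS against 8.89 in controls and Or4f60b at 6.06 against 8.06. The background of the arrays was not measured and its correction was not varied, so its part in these differences was not tested.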

Other observations

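Tests of array spread and of the clock genes' relation were chosen after the results were seen. The fit with the clock index was added after the data were seen but before its own result was known, and the splits were set before theirs. Red cell genes read higher in MetS, with the haem synthesis gene Alas2 at 10.98 ± 0.25 against 10.35 ± 0.47 (SD, 3 MetS and 4 controls) and the globin gene Hbb at 13.30 ± 0.09 against 13.01 ± 0.17, but the groups overlapped and the erythroid list was not called (camera, adjusted p = 0.111, with 0.0195 without MetS animal 1 and a call in 3 of 23 alternatives). With the SD in the fit Alas2 went from 0.63 to 0.11 and the mean of the erythroid list relative to other genes from 0.38 to 0.08 (adjusted p = 0.439), and without controls 2 and 3 they were 0.31 and 0.18. In the type I interferon list 22 of 24 genes were higher and the list was not called (adjusted p = 0.0529), with the antiviral gene Rsad2 at 8.80 ± 0.30 against 8.15 ± 0.47 and Oasl2 at 9.71 ± 0.32 against 9.28 ± 0.20. That list turned on single animals, with an adjusted p of 0.000131 without control 2, 0.00199 without MetS animal 3 and 0.00474 without control 1 but 0.574 without control 4. It was called in 7 of 24 alternatives, with the SD in the fit among them (adjusted p = 0.0146), but not with an estimated correlation (adjusted p = 0.988). In the smooth muscle list 10 of 11 were higher without a call (adjusted p = 0.0613), with the myosin gene Myh11 at 8.94 ± 0.45 against 8.57 ± 0.14. It was called in 5 of 24 alternatives, among them without MetS animal 1 (adjusted p = 0.00227) and without MetS animal 3 (adjusted p = 0.0429). Its mean relative to other genes went from 0.26 to 0.13 without MetS animal 2 (adjusted p = 0.342), to 0.06 with the SD in the fit (adjusted p = 0.365) and to 0.13 without controls 2 and 3 (adjusted p = 0.272).

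Among B cell genes the complement receptor gene Cr2 stood at 6.39 ± 0.35 against 6.84 ± 0.09 and the kinase gene Blk at 7.50 ± 0.10 against 7.72 ± 0.09, but the list had 5 genes higher and 5 lower and was not called (adjusted p = 0.352). With the SD in the fit Blk went from -0.22 to -0.07. The complement gene Cfp stood at 9.69 ± 0.13 against 9.98 ± 0.10, in a list with 13 of 18 genes higher and no call (adjusted p = 0.856). The immediate early gene Junb stood at 9.13 ± 0.12 against 9.40 ± 0.16, and Egr1 read lower too, but their list had 12 genes higher and 13 lower and was not called (adjusted p = 0.16). It was called lower in 8 of 24 alternatives, among them with the SD in the fit (adjusted p = 0.00552), without MetS animal 3 (adjusted p = 0.0075) and without control 3 (adjusted p = 0.00965), with 0.651 without MetS animal 1. The oxygen-regulated gene Hif3a stood at 7.40 ± 0.10 against 7.10 ± 0.05 and the glycolysis regulator Pfkfb3 at 9.45 ± 0.06 against 9.13 ± 0.16, which went from 0.32 to 0.14 with the SD in the fit. Their hypoxia response list had 12 genes higher and 6 lower and was not called (adjusted p = 0.81), and with the SD in the fit it was called lower, at -0.14 relative to other genes (adjusted p = 0.027). Probe 10856175, which has no gene symbol in the table used here, stood at 7.59 ± 0.56 against 3.93 ± 0.93 (limma, adjusted p = 0.324). No fold is given, since the control values, between 3.05 and 4.90, lie about the mean of 4.54 of the dimmest of 10 groups of probes, near background.

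The olfactory receptor values went with the spread of the arrays. With the SD of each animal in the fit, the median difference was 0.127 of its size, and with the SD taken without receptor probes it was 0.232, so that a relation to the spread of the arrays stays a candidate cause. Brightness alone gives less, as the 2 dimmest of 10 groups of probes had medians of -0.131 and -0.132 against -0.66 and -0.69 in the 2 receptor families, and the vomeronasal list lay at percentile 0 of lists matched on brightness. Over the 7 animals the SD without receptor probes and the olfactory median had a Pearson r of -0.975 (exact permutation p = 0.000794, adjusted p = 0.00238 over 3 relations) and a Spearman rho of -0.929 (p = 0.00675, adjusted p = 0.0203), and r was -0.93 without the 2 animals farthest from the median. This SD drops only named receptor probes, and unnamed ones such as 10722407 read lower in MetS too (7.70 ± 1.11 against 10.64 ± 1.07). The SD of all probes had an r of -0.993 with the first principal component, the main axis between animals, at 64.6% of the variance. The SD is therefore not independent of the receptor values. The relation and the smaller differences follow in part from how it was built, and do not decide the cause. No test separated the cause of the spread itself, and an effect of the diet on it stays open and untested.

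For the glucocorticoid list, time of day is argued against only as far as the clock index follows it, on a single axis in a linear fit. The labels give no times, so other effects of time of day stay open. With the clock index in the fit the mean difference from other genes was 0.278 (95% interval 0.127 to 0.428, camera adjusted p = 0.00536, 0.912 of the list mean kept). Array spread cannot be told apart from the group, since with the SD in the fit that mean was 0.213 with a 95% interval from -0.0908 to 0.517, against 0.301 (0.103 to 0.499) without it. The criterion first written, itself after the result was seen, would have argued against the spread in all 3 of its parts: camera's adjusted p was 0.039 with the SD in the fit and 0.00292 without controls 2 and 3 (mean 0.239), and the list lay at percentile 100 of lists matched on brightness. The condition that the interval exclude 0 was added after these values were seen, because camera with the preset correlation called 7 to 22 lists in every split of the animals. Chance cannot be excluded, as 2 of 35 splits gave a mean this far from the other genes, the real one at 0.3014 and the highest other at 0.3206; an effect of the diet through this hormone may remain and was not tested.

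The clock genes differed between animals of both groups, with an index of -1.273, -0.023 and 0.784 in MetS and -0.612, -0.376, 1.52 and -0.021 in controls. The mean of Dbp and its partners and that of Bmal1 and its partners had a Pearson r of -0.889 (exact permutation p = 0.00714, adjusted p = 0.0107) and a Spearman rho of -0.75 (p = 0.0663, adjusted p = 0.0881). Without the 2 animals farthest from the median r was -0.616 over a narrower range, so how far the relation rests on them is open. The negative relation could come from animals sampled at different clock phases, though the rank test did not pass and the labels give no times.

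For the count of probes at an unadjusted p under 0.05 and for the count of lists chance cannot be excluded. At least 3959 probes at an unadjusted p under 0.05 came up in 5 of 35 splits, the real one included, with 7448 as the highest other. For probes past the adjusted threshold the real count was 0, which all 35 of 35 splits must reach, so that this comparison says nothing about chance; the highest other was 1927. Both highest counts came from controls 1, 2 and 3 against the rest, which points to a structure of the samples beyond the groups. As many lists as the real 8 were called in 34 of 35 splits, with 22 as the highest other.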
